A study of Bacillus sp. (in: firmicutes) with 4 samples.

How the data were processed

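RNA was measured by sequencing in 4 libraries of Bacillus sp. CL-3, a Gram-positive spore-forming bacterium. Per the labels, 2 libraries came from cells without salt stress (called control libraries 1 and 2) and 2 from cells at 8% salt (called salt libraries 1 and 2). Per the labels' protocols, total RNA was purified on silica columns, 5S, 16S and 23S ribosomal RNA was depleted, and stranded libraries were made. Trim Galore, Bowtie2, featureCounts and DESeq2 are named in the submitters' processing notes, without versions or settings; a genome build and the strand setting of the counting are not given in the sources used here. Nothing in the labels says whether the 2 replicates of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Salt type, growth phase and time under salt are not given in the sources used here either.

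The deposited file holds 1 table of 4774 genes with a gene identifier, a product name, a gene symbol for 1085 genes, and 1 log2 value per library. The identifiers begin with FORC47, and the sources used here do not say whether that annotation was made from the CL-3 genome. Gene copies and unmatched lists therefore describe that annotation and may differ from the genes of CL-3. The authors' deposited log2 values are normalized read counts with a constant of 4 added before the logarithm, as read from the values: the lowest value is 2.0, which is log2 of 4. Removing the logarithm and the constant gave values that were whole multiples of 1 unit per library, with 100.0% of values within 0.05 of a whole number in each library. The unit was worth 0.671 and 0.880 in control libraries 1 and 2 and 0.851 and 1.92 in salt libraries 1 and 2. The factors that follow from these units (1.49, 1.14, 1.17 and 0.521) equalled, to 4 decimals, a median-of-ratios scaling recomputed from the whole numbers. The whole numbers summed to 4127320 and 3286879 in control libraries 1 and 2 and to 4521679 and 4393193 in salt libraries 1 and 2. They are called worked-back counts here, because they were obtained from values deposited on a log2 scale. Before averaging, libraries of a group were compared by a chi-square test of worked-back counts over genes with at least 20 in the pair. The 2 controls differed by a chi-square of 8689 over 4743 genes (1.83 per degree of freedom) and the 2 salt libraries by 647872 over 4721 genes (137 per degree of freedom), and all 4 were kept as separate libraries. The fixed design had assumed normalized counts on a linear scale; the test it names was kept, on the values with the logarithm removed.

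The normalised read count of a gene is 2 to the power of the deposited value, minus 4. Genes with a mean normalised read count under 10 over the 4 libraries were left out, which left 4729 genes and removed 45. The 2 groups were compared on log2(normalised read count + 1) with limma 3.58.1 in R 4.3.3 (moderated variances with a trend on the mean level, all 4 libraries, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. With 2 libraries in each group an exact rank comparison of a single gene cannot reach 0.05, so p-values rest on limma's sharing of variance between genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

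Before the data were examined, 43 lists of gene symbols were fixed for osmotic, stress, metabolic, developmental and cell-cycle functions. They were matched on the symbol or, where a gene had none, on a protein name in its product text. A list needed 3 measured members to be tested: 32 lists were tested, 6 had 1 or 2 members and are given as values, and 5 matched no gene. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list's genes with all other genes, with camera at an estimated correlation, and with fry, each two-sided and Benjamini-Hochberg adjusted over the 32 lists. The rule for named genes was also set then. It takes up to 12 genes in each direction among those past the threshold with groups that do not overlap and a mean of at least 50 in the higher group. It also takes, for each list, up to 4 members past the threshold or, with none past it, the 2 members with the smallest unadjusted p, as values. The first part named no gene here. A named gene outside the rule is said to have been chosen after its values were seen. Depth was not tied to gene length, since gene lengths were not used here, and values compare a gene between libraries, not genes with each other.

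The limma script was tested on simulated data for this comparison: worked-back counts of 4729 genes were drawn at the control means with 200 genes changed, in 5 runs. With the spread of the control pair in all 4 libraries, 94.1% of genes changed 2-fold, 99.4% changed 4-fold and 99.7% changed 8-fold were found, with 8 false calls per run. With the spread of the salt pair in the salt libraries, 0% of genes changed 2-fold, 25.5% changed 4-fold and 42.6% changed 8-fold were found, with 2.8 false calls per run. Alternatives set before the data were examined were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50, 3 other scalings, limma without the trend or with robust moderation, a minimum log2 change of 1, the replicate number as a block, and each library left out. Alternatives chosen after seeing the data were the deposited log2 values as they stand, limma's voom on the worked-back counts, and the 2 control libraries counted as 1.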

Results

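Gene expression of Bacillus sp. CL-3 was measured by RNA sequencing in 2 libraries from cells without salt stress and 2 libraries from cells at 8% salt. The comparison asks which genes differ in RNA level between cells under salt and cells without it. Worked-back counts over genes totalled 4127320 and 3286879 in control libraries 1 and 2 and 4521679 and 4393193 in salt libraries 1 and 2. The median gene had 491, 378, 393 and 159 worked-back counts in the same order. No gene was listed at 0 in control library 1 or salt library 1, 1 gene in control library 2 and 14 genes in salt library 2.

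Of the 32 gene lists tested, 12 ranked higher under salt and 3 ranked lower than the remaining genes by limma camera with the preset correlation (adjusted p under the threshold), and none passed with an estimated correlation. The higher lists included glycolysis with pyruvate dehydrogenase, the tricarboxylic acid cycle, translation factors, chaperones, fatty acid synthesis, cell division and motility. The lower lists were sporulation, branched-chain amino acid synthesis and competence. In control library 1 the median gene had a normalised read count of 330. The 12 higher lists had medians there from 351 to 3177. Sporulation (273) and competence (221) lay below the median gene, and branched-chain amino acid synthesis (589) above. How far the ranking of lists follows level was not tested directly. With the estimated correlation the smallest adjusted p was 0.683. That estimate rests on 2 residual degrees of freedom, whose spread came mostly from the 2 salt libraries. It was 0.221 for sporulation, 0.722 for motility and 0.999 for translation factors and branched-chain amino acid synthesis. With estimates near 0.999 a list could hardly pass, so its failure there decides nothing. Estimates this far above the preset correlation also mean that the preset p-values may be too small. No list passed fry, whose smallest adjusted p was 0.316. No single gene passed in either direction: 0 genes were higher and 0 were lower among 4729 (limma, smallest adjusted p = 0.3). At an unadjusted p under 0.05 there were 270 genes, all of them higher under salt. Evenly spread p-values would put 236 genes there, but the smallest unadjusted p was 0.0185 (limma), so 236 is no firm reference. The split into higher and lower genes depended on the setting: 863 genes were higher and 529 lower at an unadjusted p under 0.05 after quantile normalization, and 502 higher and 189 lower with the replicate block. The voom test on worked-back counts also called 0 genes, with 853 at an unadjusted p under 0.05. The 2 salt libraries differed far more than the 2 controls: the median SD of a gene on the log2 scale was 0.584 in the salt group and 0.039 in the control group (n = 2 each). Over all tested genes, both salt libraries lay above both controls in 42.8% and below both in 47.3%. Values of salt library 1 lay close to a weighted sum of control library 1 and salt library 2. Counts of list members higher or lower in both salt libraries may therefore not rest on 2 separate observations.

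**Figure D1:**
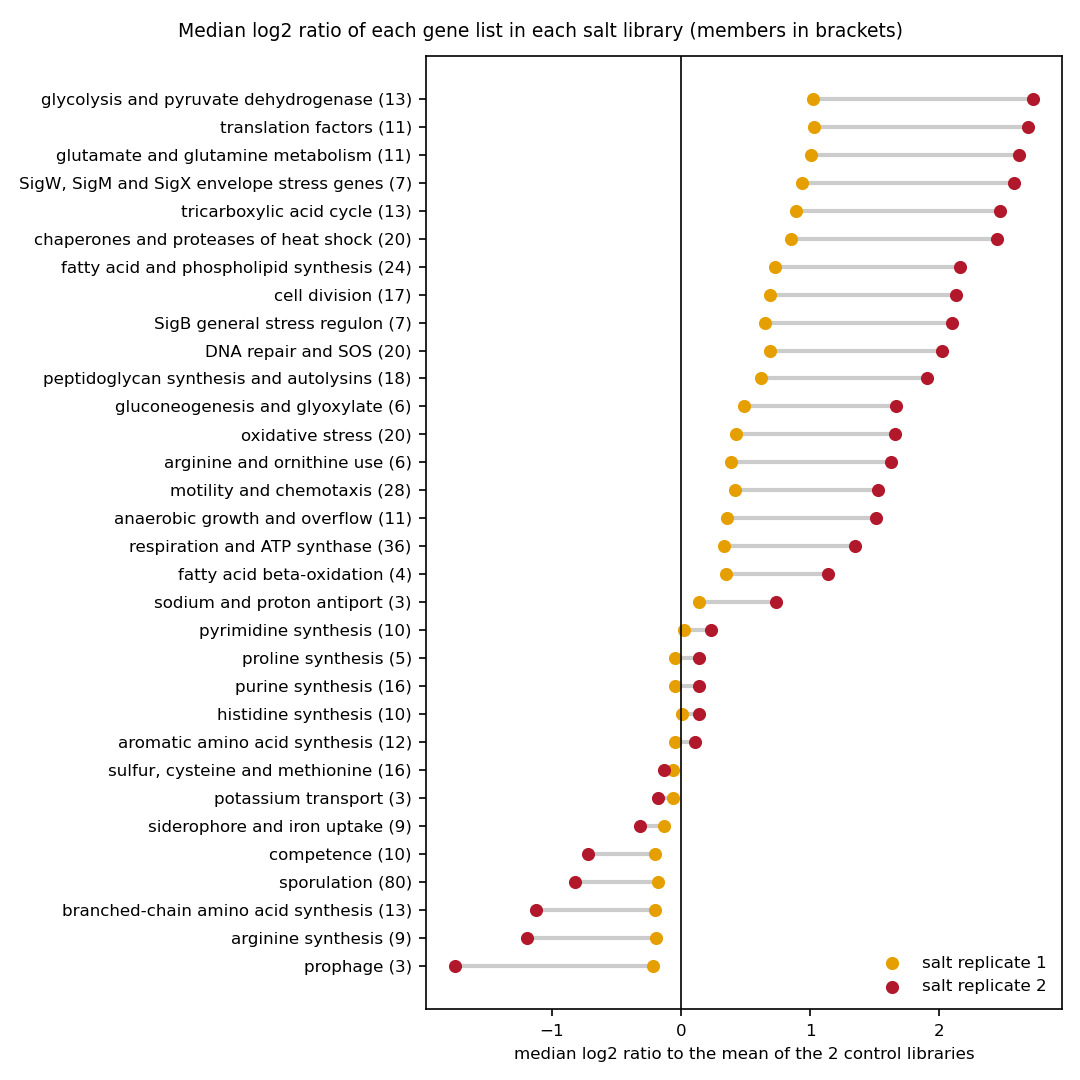
Median log2 ratio of normalised read count to the mean of the 2 control libraries (horizontal axis) for the members of each tested gene list (vertical axis, number of members in brackets), with 1 point for each salt library and a grey line joining the 2. For glycolysis and pyruvate dehydrogenase the 2 salt libraries lie at 1.02 and 2.73, and for branched-chain amino acid synthesis at -0.20 and -1.12.

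The genes most directly tied to salt gave mixed values. Both copies of opuD, a glycine betaine transporter, had higher normalised read counts in each salt library than in either control. FORC47_RS02915 had 1705 and 1935 in the controls against 3051 and 8617 under salt, a log2 fold change of 1.50 ± 0.70 (SE, n = 2 per group; limma adjusted p = 0.3), which fell to 0.06 under quantile normalization. FORC47_RS26990 had 1720 and 1998 against 2964 and 8306, a log2 fold change of 1.42 ± 0.70, which turned to -0.04 under that normalization. The 2 copies had nearly equal values in every library, and reads shared between them cannot be separated here. The sodium/proline symporter gene putP (FORC47_RS18790) had 3043 and 3484 in the controls and 6844 and 22126 under salt, with a log2 fold change of 1.92 ± 0.85 that fell to 0.31 under quantile normalization. A second putP gene (FORC47_RS06355) had 818 and 844 against 898 and 1372, and its log2 fold change of 0.42 ± 0.39 turned to -0.36. The 5 proline synthesis genes went both ways: proC stood at 1.71 ± 0.63 and proI at -0.77 ± 0.42 (0.74 and -0.55 under quantile normalization), and the list did not differ from other genes (camera adjusted p = 0.938; its median of 0.05 and its test differed in sign). The 3 nhaC genes, for sodium/proton antiporters, had a median log2 fold change of 0.44, not apart from other genes (camera adjusted p = 0.294). Their median relative to all genes fell from 0.46 to 0.01 under quantile normalization. Of the 3 kdp genes for the potassium-transporting ATPase, kdpB had 882 and 886 in the controls and 827 and 751 under salt, and kdpC had 173 and 160 against 175 and 204. Their log2 fold changes, -0.17 ± 0.32 and 0.18 ± 0.22, were smaller than their errors, and under quantile normalization they moved to -0.78 and 0.41. The channel gene mscL, which opens when the membrane is stretched, had 279 and 312 in the controls and 421 and 1049 under salt, and the glycerol facilitator gene glpF had 567 and 582 against 659 and 1124. Their log2 fold changes went from 1.17 to 0.93 and from 0.58 to 0.08 under quantile normalization. No gene matched the lists for choline conversion or ectoine synthesis.

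**Figure D2:**
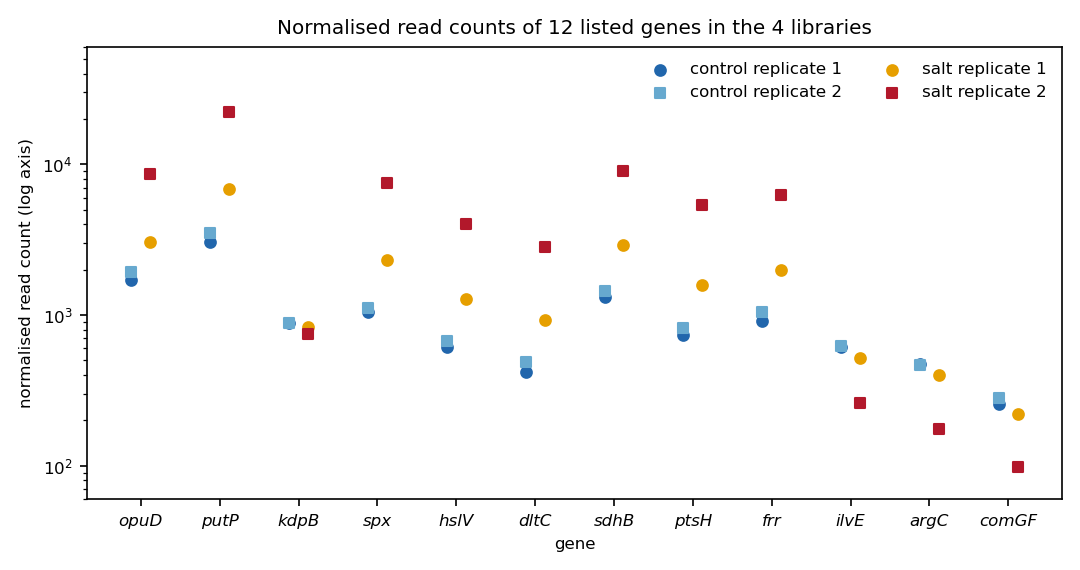
Normalised read counts (vertical log axis) of 12 genes taken from the lists, with 1 point per library: control replicates in blue and salt replicates in orange and red. The putP gene shown is FORC47_RS18790, at 3043 and 3484 in the controls and 6844 and 22126 under salt, while kdpB lay between 751 and 886 in all 4 libraries.

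Of 20 chaperone and heat-shock protease genes, 17 were higher in both salt libraries than in both controls and 3 were lower, with a median log2 fold change of 1.63 (camera adjusted p = 0.000825; adjusted p = 0.683 with an estimated correlation). The protease subunit gene hslV had 608 and 673 in the controls and 1283 and 3984 under salt, and ctsR, a repressor of heat-shock genes, had 667 and 729 against 1289 and 3498. Of 20 oxidative stress genes, 18 were higher in both salt libraries (median 1.05; camera adjusted p = 0.000266; adjusted p = 0.683 with an estimated correlation). Among them the thioredoxin gene trxA stood at 1.93 ± 0.69, and the regulator gene spx, also in the SigB list, at 1.96 ± 0.70. Of 7 genes matched by name to the SigB general stress list, 6 were higher in both salt libraries (median 1.37, camera adjusted p = 0.019, or 0.683 with an estimated correlation). Control of these genes by SigB was not tested in this strain. The 6 included a YtxH domain protein gene (FORC47_RS05455), matched through the domain name in its product text, with 337 and 410 in the controls and 690 and 2075 under salt. The 7 envelope stress genes had a median of 1.76 without passing (camera adjusted p = 0.0827; adjusted p = 0.683 with an estimated correlation). The list passed at the preset correlation with equal column totals (0.00759), quantile normalization (0.027), without salt replicate 1 (0.0489) and without salt replicate 2 (0.00933). Its median relative to all genes fell from 1.79 to 0.41 with quantile normalization. The largest log2 fold changes in this list came from the dlt operon, which adds D-alanine to teichoic acids: dltC stood at 1.85 ± 0.62 and dltB at 1.88 ± 0.65. The 20 DNA repair and SOS genes all had a log2 fold change above 0 (median 1.36; camera adjusted p = 0.000113; adjusted p = 0.683 with an estimated correlation; 0.216 at the preset correlation after quantile normalization), with the SOS repressor gene lexA at 1.85 ± 0.70 and recF at 1.80 ± 0.69.

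All 13 glycolysis and pyruvate dehydrogenase genes were higher in both salt libraries than in both controls (median 1.88; camera adjusted p = 0.000751; adjusted p = 0.683 with an estimated correlation); with salt library 2 as the only salt library the adjusted p was 0.0708. The sugar phosphotransferase gene ptsH had 733 and 818 in the controls and 1592 and 5358 under salt. All 13 tricarboxylic acid cycle genes were also higher in both salt libraries (median 1.69; camera adjusted p = 0.000197; adjusted p = 0.683 with an estimated correlation), with the succinate dehydrogenase gene sdhB at 1.90 ± 0.71 and the malate dehydrogenase gene mdh at 1.67 ± 0.63. Of 36 respiration and ATP synthase genes, 30 were higher and 2 lower in both salt libraries (median 0.84; camera adjusted p = 0.000197; adjusted p = 0.712 with an estimated correlation). The ATP synthase subunit genes atpF and atpC stood at 1.63 ± 0.60 and 1.63 ± 0.62. All 11 translation factor genes were higher in both salt libraries (median 1.86; camera adjusted p = 0.000825; adjusted p = 0.683 with an estimated correlation). Ribosome recycling factor, frr, had 911 and 1038 in the controls and 1986 and 6280 under salt, and elongation factor P, efp, had 724 and 843 against 1466 and 4290.

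Cell surface, division and movement genes followed. Of 24 fatty acid and phospholipid synthesis genes, 18 were higher and 5 lower in both salt libraries (median 1.44; camera adjusted p = 0.00141; adjusted p = 0.683 with an estimated correlation), with fapR, the repressor of the pathway, at 1.77 ± 0.62 and the acetyl-CoA carboxylase gene accB at 1.70 ± 0.61. Of 18 peptidoglycan and autolysin genes, 17 were higher (median 1.27; camera adjusted p = 0.000431; adjusted p = 0.683 with an estimated correlation), and of 17 cell division genes, 16 were higher (median 1.41; camera adjusted p = 0.000197; adjusted p = 0.683 with an estimated correlation). Their smallest unadjusted p-values belonged to uppS and mreC, at 1.63 ± 0.60 and 1.81 ± 0.72, and to gpsB, at 1.74 ± 0.59. Of 28 motility and chemotaxis genes, 26 were higher in both salt libraries (median 1.02; camera adjusted p = 6.61e-05; adjusted p = 0.683 with an estimated correlation); the chemotaxis methyltransferase gene cheR had 181 and 183 in the controls and 315 and 811 under salt.

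On the lower side, all 13 branched-chain amino acid synthesis genes were lower in both salt libraries than in both controls (median -0.66; camera adjusted p = 0.000922; adjusted p = 0.683 with an estimated correlation; 0.0596 at the preset correlation with equal column totals). The aminotransferase gene ilvE had 611 and 626 in the controls and 522 and 261 under salt, and ilvN, for the small subunit of acetolactate synthase, had 191 and 186 against 164 and 71.1. Of 80 sporulation genes, 58 were lower and 16 higher in both salt libraries (median -0.50; camera adjusted p = 0.000798; adjusted p = 0.683 with an estimated correlation). The 2 members with the smallest unadjusted p went against the list: the germination gene gerPF (FORC47_RS11360) stood at 1.44 ± 0.48 and spoVG, a regulator active before sporulation, at 1.25 ± 0.46. Of 10 competence genes, which serve DNA uptake, 9 were lower in both salt libraries (median -0.45; camera adjusted p = 0.0257; adjusted p = 0.683 with an estimated correlation). The competence call was lost at the preset correlation with equal column totals (0.138), quantile normalization (0.162), without control replicate 1 (0.0517) and with the replicate block (0.0508). In this list comGF had 257 and 282 in the controls and 220 and 98.0 under salt.

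The other lists did not pass camera in the main test. Glutamate and glutamine metabolism held 7 genes higher and 4 lower in both salt libraries (median 1.82, adjusted p = 0.294; 9.89e-05 with equal column totals; 0.683 with an estimated correlation), with the asparaginase gene ansA at 1.93 ± 0.65 and the repressor gene glnR at 2.01 ± 0.81. With quantile normalization the list's median relative to all genes fell from 1.85 to 0.24, ansA to 0.83 and glnR to 0.45. The 6 arginine and ornithine use genes had a median of 1.01 (adjusted p = 0.107; 0.035 without the trend; 0.712 with an estimated correlation), and rocD stood at 1.33 ± 0.60. With quantile normalization that list's median relative to all genes turned from 1.03 to -0.10 and rocD fell to 0.17. The 9 arginine synthesis genes had a median of -0.69 (adjusted p = 0.202; 0.00365 with quantile normalization and 0.0489 without salt replicate 1; 0.683 with an estimated correlation), and argC had 473 and 464 in the controls and 397 and 175 under salt. Medians were 1.08 for gluconeogenesis and glyoxylate (adjusted p = 0.09), 0.93 for anaerobic growth and overflow (0.217), 0.75 for fatty acid beta-oxidation (0.359), -0.22 for siderophore and iron uptake (0.359) and -0.99 for the 3 prophage genes (0.685). With quantile normalization, relative to all genes, gluconeogenesis and glyoxylate stood at 0.05, beta-oxidation at 0.05, and anaerobic growth and overflow turned to -0.42. By the same measure siderophore and iron uptake went from -0.20 to -0.03 and prophage from -0.96 to -0.49. Lists with medians near 0 were pyrimidine synthesis at 0.13 (0.685), histidine synthesis at 0.09 (0.745), purine synthesis at 0.05 (0.897), aromatic amino acid synthesis at 0.03 (0.745), potassium transport at -0.12 (0.933) and sulfur, cysteine and methionine at -0.10 (0.938); for the aromatic and the sulfur list the median and the test differed in sign. No member of any of the 32 lists passed, over all genes or adjusted over the list alone (limma). Of lists with 1 or 2 members not yet given, rpmG, annotated as a pseudogene and the only match of the ribosomal protein list, stood at 1.15 ± 0.43. The secondary metabolite list matched sfp, at 0.17 ± 0.24, and ppsA, at -0.03 ± 0.23. The ppsA product is annotated as phosphoenolpyruvate synthase, so that gene matched the list by its symbol only. The secreted enzyme genes amyS and nprB stood at -0.70 ± 0.43 and -0.62 ± 0.43 (-1.10 and -1.26 under quantile normalization). Biofilm matrix genes, aminoacyl-tRNA synthetases and ribosomal RNA were not analysed here, as no gene matched those lists.

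The 2 salt libraries differed in the size of their changes. Both salt libraries lay above both controls in 2022 genes (42.8%) and below both in 2236 genes (47.3%), where chance gives 16.7% in each direction if the 4 libraries are separate. The values of salt library 1 lay close to a weighted sum of control library 1 and salt library 2 (weights 0.762 and 0.206, residual SD 0.047 log2 units). Whether its agreement with salt library 2 is independent replication was left open. Salt library 1 held 149 genes at 2-fold or more above the control mean and 0 at 2-fold or more below it. Salt library 2 held 1467 genes above and 1001 below by that measure, and all 149 were among the 1467. Across genes, which are not independent replicates, the log2 ratios of the 2 salt libraries to the control mean had a Pearson correlation of 0.951 and a covariance of 0.479. Unchanged libraries simulated against shared controls gave 0.33 and 0.0025. With salt library 2 as the only salt library, limma called 2201 genes higher and 2185 lower, and with salt library 1 alone 1639 higher and 1483 lower. These fits assume that the lone library varies like the controls, so they compare those libraries and not the conditions. They shared 1638 genes higher and 1473 lower, and both fits use the same controls.

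**Figure D3:**
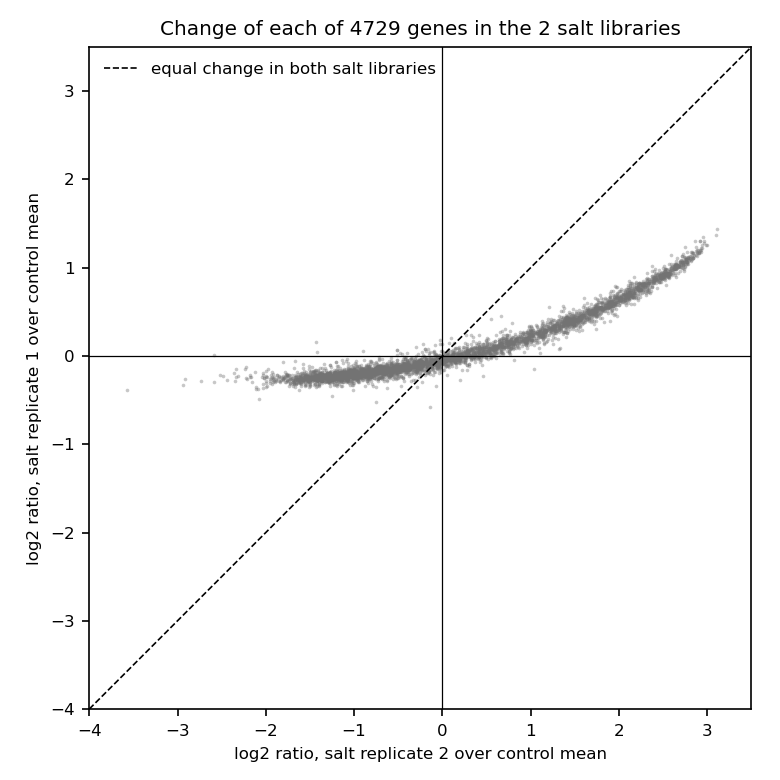
Log2 ratio of normalised read count to the control mean for each of 4729 genes in salt library 2 (horizontal axis) and salt library 1 (vertical axis), 1 point per gene, with a dashed line of equal change. The points run along a curved band flatter than the dashed line, between -0.58 and 1.44 for salt library 1 and between -3.57 and 3.11 for salt library 2.

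The direction of a change also depended on the scaling. Normalised read counts summed to 2771211 and 2892342 in the controls and to 3849788 and 8439161 in the salt libraries. Scaling the libraries to equal totals moved the median log2 fold change of all genes from -0.02 to -1.03 and the share of genes above 0 from 49.1% to 20.4%, with 0 genes called in each case (limma). All 15 lists that passed kept their camera direction under that scaling. Their medians relative to all genes could hardly move, because 1 factor per library shifts every gene by nearly the same amount. Those relative medians are therefore no check of the scaling. Of the 12 higher lists, 1 then had a median below 0, respiration and ATP synthase (-0.17). Motility and chemotaxis (0.01) and oxidative stress (0.04) then had medians near 0. Quantile normalization, which gives all libraries the same distribution of values, changed the sizes: relative to all genes, the medians of the 12 higher lists ran from 0.86 to 1.91 in the main test and from 0.12 to 0.80 after it. Glycolysis and pyruvate dehydrogenase went from 1.91 to 0.22, the tricarboxylic acid cycle from 1.72 to 0.21, chaperones from 1.66 to 0.21, and peptidoglycan synthesis from 1.29 to 0.19. The SigB list went from 1.40 to 0.80 and motility from 1.04 to 0.72. Of the 3 lower lists, branched-chain amino acid synthesis went from -0.64 to -0.84, sporulation from -0.48 to -0.34 and competence from -0.42 to -0.22. Of 51 named genes with a log2 fold change of at least 1 in size, 15 kept that size. The directions and sizes given above are those relative to the median gene of the authors' scaling.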

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

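The settings with the deposited log2 values, voom and the controls counted as 1 library were chosen after the data were seen. The counts of 0 genes higher and 0 lower held under the other pseudocounts, filters, scalings and moderation settings, the deposited log2 values and voom (limma). There were 176 to 1392 genes at an unadjusted p under 0.05 among settings that kept the 4 libraries apart and had no block. With the controls counted as 1 library, the spread rests on the salt pair alone, so that setting could hardly have called a gene. The minimum log2 change of 1 reused the main fit, so it could add no gene and change no list. Repeating the median-of-ratios scaling hardly changed the values, with 269 against 270 genes at an unadjusted p under 0.05 (limma). Leaving out each library in turn gave 0 to 2201 genes higher and 0 to 2185 lower: counts above 0 came only from the fits with 1 salt library, where the spread rests on the 2 controls alone. With the replicate block, 1 gene was higher and 0 were lower; it was FORC47_RS19015, a DUF896 domain protein gene named after its values were seen (limma adjusted p = 0.0461). Replicate numbers do not establish pairs here (deviations of libraries with the same number correlated at 0.48 across genes, from 2 pairs). The number of lists past camera was 15 and lay between 14 and 16 under every setting, and all 15 kept their direction. Calls among lists were lost or gained with equal column totals and quantile normalization (2 lost and 2 gained in each), no trend (1 gained), the block (1 lost), without control replicate 1 (1 lost), without salt replicate 1 (1 lost, 2 gained) and without salt replicate 2 (1 gained).

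Direction turned only for results past no threshold in the main test; the cause was not tested. Given as the log2 median less that of all genes, the lists whose camera direction turned were, with equal column totals, sodium and proton antiport (0.459), histidine synthesis (0.114) and purine synthesis (0.066). With quantile normalization they were sodium and proton antiport (0.01), anaerobic growth and overflow (-0.418), arginine and ornithine use (-0.101), sulfur, cysteine and methionine (-0.088) and purine synthesis (-0.144). The sulfur list also turned with a minimum mean of 50 (-0.108) and with the controls counted as 1 library (-0.073). Leaving out each library turned 4 lists at least once, with values from -0.13 to -0.021 for sulfur, -0.177 to -0.014 for potassium transport, 0.055 to 0.142 for histidine synthesis and -0.003 to 0.146 for purine synthesis. Of 74 named genes, 5 turned with quantile normalization: opuD FORC47_RS26990 to -0.042, putP FORC47_RS06355 to -0.357, nhaC FORC47_RS01980 to -0.015, rocF to -0.012 and ppsA to 0.021; ppsA ranged from -0.083 to 0.017 with each library left out. The count tests edgeR and DESeq2 were not run on the worked-back counts, and voom was the only count model used. The fixed design named edgeR only for a file of raw counts, which did not apply. Depth limits low genes most in salt library 2, where 1 worked-back count is worth 1.92 normalised counts.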

Other observations

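The groups in this part and every test in it were chosen after the values were seen; directions are relative to the median gene of the authors' scaling. The 5 genes for RNA polymerase subunits, which make all cellular RNA, were higher in both salt libraries than in both controls, with log2 fold changes between 1.76 and 2.07 (limma, smallest adjusted p in the group 0.3). So were the 6 protein export genes, with a median of 1.28, and the 6 cold shock protein genes, with a median of 1.71. The 6 genes of haemolysin BL and the non-haemolytic enterotoxin, toxins known from the Bacillus cereus group, were all higher in both salt libraries as well. hblC had 1286 and 1396 in the controls and 3146 and 9029 under salt, while hblA had 423 and 453 against 456 and 586. Quantile normalization left medians of 0.30 for RNA polymerase, 0.60 for protein export, 0.84 for cold shock proteins and 0.24 for the toxin genes. Other genes with large log2 fold changes were a flagellin gene (FORC47_RS08600), at 2.15 ± 0.63 (1.35 after quantile normalization), and fabF, of fatty acid synthesis, with 2686 and 2876 in the controls and 6845 and 20979 under salt (log2 fold change 2.11, and 0.56 after quantile normalization).

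Lower in both salt libraries were the 3 genes annotated as a glycine betaine ABC transporter, with a median of -0.98, opposite to the values of the opuD transporter genes. Its ATP-binding protein gene (FORC47_RS14245) had 597 and 598 in the controls and 495 and 161 under salt. Of 10 exosporium protein genes, for the outermost layer of the spore, 9 were lower in both salt libraries, and exsG had 71.8 and 67.8 in the controls and 57.0 and 9.60 under salt. Of 16 small acid-soluble spore protein genes, 9 were lower and 3 higher in both salt libraries, where 47.3% of all genes were lower and 42.8% higher. Small stable RNAs took 8.09% and 7.46% of worked-back counts in control libraries 1 and 2 and 5.60% and 2.29% in salt libraries 1 and 2. Within that group both copies of ssrS (6S RNA, which binds RNA polymerase) were lower under salt and rnpB, the RNA of ribonuclease P, was higher, with 9396 and 10490 in the controls and 19782 and 61772 under salt. The ssrS copies went from -0.78 and -1.11 to -2.16 and -2.62 with quantile normalization, and rnpB to 0.15. Medians went from -0.98 to -0.63 for the glycine betaine ABC transporter, from -0.83 to -0.39 for the exosporium genes and from -0.45 to -0.06 for the small acid-soluble spore proteins. Of 4 genes of TrkH and TrkA family potassium uptake, which the potassium list did not match, 3 were higher and 1 lower in both salt libraries, with a median log2 fold change of 0.53 (0.04 after quantile normalization). FORC47_RS06850 of that group had 684 and 702 in the controls and 905 and 1952 under salt. None of these genes passed the adjusted threshold (limma).

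Salt library 1 lay between the controls and salt library 2 in most genes, along a narrow curve. A wrong scaling factor is argued against: the SD over genes of the log2 ratio of the 2 salt libraries, which a factor leaves unchanged, was 0.94 against 0.089 for the 2 controls. A graded response would have each gene make the same share of its log2 change. A line in log2 ratios, fitted for it, left a residual SD of 0.121. The control pair, at 0.089, cannot judge that residual. Its chi-square per degree of freedom was 0.558 outside the genes with the highest counts, closer than counting noise allows. That residual alone therefore leaves a graded response open, though the line followed salt library 1 less closely than the weighted sum given next. Over 2373 genes changed at least 2-fold in salt library 2, the median log2 share was 0.313 for higher and 0.177 for lower genes. The interquartile range within a direction averaged 0.066. The line left median residuals of 0.007 for the higher and 0.1 for the lower genes. These values argue against 1 log2 share for all of these genes. A response with unlike shares was not tested. A candidate explanation is mixing in 1 proportion: 0.762 of control library 1 plus 0.206 of salt library 2, with as many fitted parameters, left a residual SD of 0.047 over 4533 genes. A separate measure used the control mean, weights forced to sum to 1, and 2373 genes changed at least 2-fold in salt library 2. By that measure, on the linear scale, the median share differed by direction: 0.187 for genes higher in salt library 2 and 0.251 for genes lower. The free weights do not sum to 1, so forcing them can itself set the 2 directions apart. With free weights, the weighted sum left median residuals of -0.002 log2 units for higher and 0.005 for lower genes. Whether such mixing lay in the culture, as cells that had and had not responded, or arose after sampling cannot be told apart. The labels name no batch, and the worked-back counts do not settle it. Separate reads of mixed cells would give a squared residual of 1 or more times the counting variance, against 0.25 found. Numbers scaled down before normalization may also give such a ratio, as set out below. Control library 2 also took a weight of 0.022 from salt library 2. A biological difference between the 2 salt samples stays open and untested.

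Levels spread less over genes in the control libraries, with an SD of log2 values of 1.48 and 1.51, than in salt libraries 1 and 2, with 1.68 and 2.31. Genomic DNA as the whole of the control profile is argued against, since genes over 16 times the median gene took 20.6% and 21.1% of the controls' counts, and ssrA, the transfer-messenger RNA, stood at 476 times the median in control library 1. Genomic DNA as a part of it stays open: pairs of genes with the same name differed by a median of 0.69 log2 units in control library 1, against 0.97 for adjacent and 1.28 for random pairs, and by 1.35, 1.27 and 2.14 in salt library 2. Gene length would bring same-named genes together in RNA too, and gene lengths and strand were not used here. A state of the unstressed cells with smaller differences between genes was not tested.

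The worked-back counts followed weighted sums of other libraries more closely than counting noise allows. Separate reads counted in each library are argued against, because the squared residual of salt library 1, predicted from control library 1 and salt library 2, was 0.25 of the counting variance outside the 10% of genes with the highest counts, where separate reads would give 1 or more. The ratio was 0.4 for salt library 1 predicted from control library 2 and salt library 2, and also 0.4 for control library 2 predicted from control library 1 and salt library 2. Numbers scaled down and rounded before normalization may give such ratios, and so may reads shared between libraries, and these cannot be told apart without the reads. The chi-square per degree of freedom between the 2 controls was 0.558 outside those 10% of genes and 1.83 over all genes, and they were kept as 2 libraries. Counting them as 1 could not check that choice, because the spread then rests on the salt pair alone.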
